A study of Rattus norvegicus with 18 samples.

How the data were processed

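Total RNA from the liver of Sprague Dawley rats had been measured on 18 Affymetrix Rat Transcriptome 1.0 arrays, 3 at each of 6 ages. The ages were embryonic day 21 (E21, fetuses taken by C-section and killed before breathing) and 30 min, 4 h, 12 h, 1 day and 7 days after birth. The series design gives 3 dams per age, so replicates come from separate dams, and the p-values describe spread between these samples. The labels do not say how many pups made up a sample, nor their sex, and give a replicate number with no stated meaning. Deviations from the age means of same-numbered arrays correlated at 0.107 to 0.292 between E21 and 4 h and at 0.15 to 0.298 between 4 h and 12 h. All 3 pairs of these 2 comparisons were over 0.1, and in each of the other 7 comparisons at least 1 pair was not. That is a hint from the data and not from the design. Between E21 and 12 h, both tied to 4 h in this way, same-numbered arrays correlated at −0.142 to −0.031. The numbers are therefore not shown to pair the arrays. A block in these 2 comparisons was used as an alternative only, chosen after the values were seen.

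The deposited values are intensities per transcript cluster, a probe set that covers a whole gene. Per the submitters' processing notes the authors used RMA and Affymetrix Expression Console 1.0, with no role or order given for either. The annotation release and any filter were not given in the sources used here. RMA usually returns log2 values, but the deposited intensities were linear, ran from 4.24 to 999969 and had array medians between 61.9 and 65.5. On every array 186 features lay above 65535, the largest value of a 16-bit scanner, and nothing in the notes explains that scale. Folds and log2 changes are therefore those of the deposited scale, and their relation to the signal the scanner read is not known. In addition, 13 genes lay within 0.1 log2 of the highest value on all 18 arrays, 27 did so on at least 1, and a change in such a gene could not be measured. At the lower end no detection call was used here. Y-linked genes on arrays without Y-linked expression and the pancreas list before 7 days, taken to be silent, gave 189 readings from 3.74 to 6.72, where array medians over genes were 6.28 to 6.39. In 28 of 226 calls of named genes all 3 arrays of the dimmer age lay at or below 6.72, and in 21 more 1 or 2 did. Those of the 28 that are printed, and the changes of Cyp1a2, Inhbe and Anks4b among the 21, carry a lower bound in which arrays below 6.72 are set to it. The bound was chosen after the values were seen and is rough, since probe sets differ in background.

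The table held 24753 features. One gene symbol was given for 19837 of them, several symbols for 420 and none for 4496, and the last 2 kinds were kept out of the gene tests. The Entrez identifier of 19230 features was found in the reference gene table, which updated 1 symbol. For 800 genes with more than 1 feature the brightest was used, which left 18926 genes. No genome positions were used. The log2 of the deposited intensities was taken with no added constant and no further normalization. The plan, fixed before the data were examined, had assumed that the values were already on the log2 scale.

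Each gene was fitted with limma 3.58.1 under R 4.3.3 as a mean per age over all 18 arrays, with moderated standard errors from eBayes (12 residual and 3.05 prior degrees of freedom). Each later age was compared with E21, each age with the one before it, and all ages together by the moderated F test. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. A count of genes higher at 30 min for a time only (past the threshold and higher at 30 min against E21, and past it and lower at 4 h against 30 min) was made as well. The 3 arrays per age limit the precision. In data simulated on this design with known changes, limma found 77.6% to 92.5% of those of 1 log2 and all of 4 log2. It made 7 to 9 false calls per comparison and called none in the wrong direction. The list test found the 1 simulated list and no other. Genes were drawn independently, which leaves correlation within a list uncovered. Whether those shares hold on the uneven real arrays was not tested.

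Gene lists, 34 in all with 647 entries of which 602 were matched (3 by synonym), were fixed before the data were examined, as were the comparisons, the test and most alternatives. They were immediate early genes, gluconeogenesis, glycogen metabolism, glycolysis, fatty acid oxidation and ketogenesis, PPAR alpha targets, lipogenesis, cholesterol synthesis, bile acid synthesis and transport, urea cycle, amino acid catabolism, cytochromes P450 and conjugation, fetal and imprinted growth genes, cell cycle, acute phase proteins, heat shock proteins, the unfolded protein and ATF4 response, hypoxia response, circadian clock, glucocorticoid-induced genes, ribosome biogenesis, hepatocyte plasma proteins and the growth hormone and IGF axis. Marker lists covered erythroid, neutrophil, platelet and megakaryocyte, macrophage, B, T and NK, stellate and mesenchymal, endothelial, cholangiocyte, pancreas and skeletal muscle cells. Each list was compared with all other genes by camera at its preset correlation of 0.01, adjusted over the 34 lists of a comparison, and again with a correlation estimated from the residuals. The fry test was run as an alternative: it asks whether a list's genes move on balance one way, and does not compare them with other genes. Members were also adjusted over the list alone.

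The genes to be named followed a rule fixed before the data were examined. For each age against E21 these were the 6 largest rises and 6 largest falls among genes past the threshold whose 3 arrays all lay on one side of all 3 arrays of the other age. For the other 4 steps between successive ages they were the 3 largest each way. For each list, the 2 members past the threshold with the largest absolute change in each comparison with E21 were added, or, where none passed at any age, the member with the largest absolute change at 7 days. Uncharacterized loci were skipped, Afp, Alb, Pck1 and G6pc1 were reference genes at all ages, and 161 genes were named in all. Any other gene named was chosen after its values were seen.

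The alternatives fixed at that time were equal array medians, quantile normalization again, leaving out dim genes, testing every feature, the mean of a gene's features, a fit of only the 6 arrays compared, a trended and robust prior, array weights, the replicate number as a block, a log2 change of at least 1, the estimated correlation, fry, and leaving out each array in turn. Chosen after seeing the data were the replicate number as a block within the 2 ages compared, for the 2 comparisons it pairs, a covariate of Y-linked expression (the log2 level of Ddx3y), leaving out E21 replicate 1, 30 min replicate 3 and 4 h replicate 3 together, leaving out 7 days replicates 2 and 3 together, and leaving out genes near the upper limit. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.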

Results

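Liver RNA of rats was profiled across birth on 18 arrays, 3 for each of 6 ages, from E21 fetuses through 30 min, 4 h, 12 h and 1 day to 7 days of life. Pearson correlations over genes ran from 0.987 to 0.994 between arrays of one age and from 0.948 to 0.993 between ages. The first principal component held 38.5% of the variance and set the 3 arrays of 7 days (61.5 to 73.9) apart from the other 15, and the second, with 17.5%, held the 12 h and 1 day arrays (−35.8 to −25.6) below all others. Of 18926 genes, 5931 (31.3%) passed the limma test over all ages. Values below are log2 changes with the moderated standard error of limma, n = 3 arrays per age, on the scale of the deposited intensities, whose upper range the submitters' notes do not explain. No detection call was used here, so a change written with "at least" sets the arrays of the dimmer age to no less than 6.72, the highest reading of genes taken to be silent.

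Alb and Afp, the main plasma proteins of adult and fetal liver, lay at the upper limit of the values at every age (19.93 at E21 and 19.92 at 7 days), so any change in them could not be measured. Pck1 and G6pc1, key enzymes of glucose production, were the other reference genes. Pck1 read 1.96, 3.4, 2.84, 3.4 and 1.92 above E21 at the 5 successive ages, with a standard error of 1.13, and passed at none of them (adjusted p = 0.766, 0.107, 0.186, 0.105 and 0.275). It passed at 4 h with the replicate number of the 2 ages as a block (0.0362), an alternative chosen after the data were seen. Its E21 arrays read 18.06, 12.87 and 12.48, and the array with the high value, E21 replicate 1, also read high for 2 amino acid catabolism genes, Tat (17.95 against 11.02 and 14.43) and Sds (14.69 against 7.53 and 7.77). Tat was chosen after its values were seen. G6pc1 passed only at 7 days, where it was lower.

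**Figure D1:**
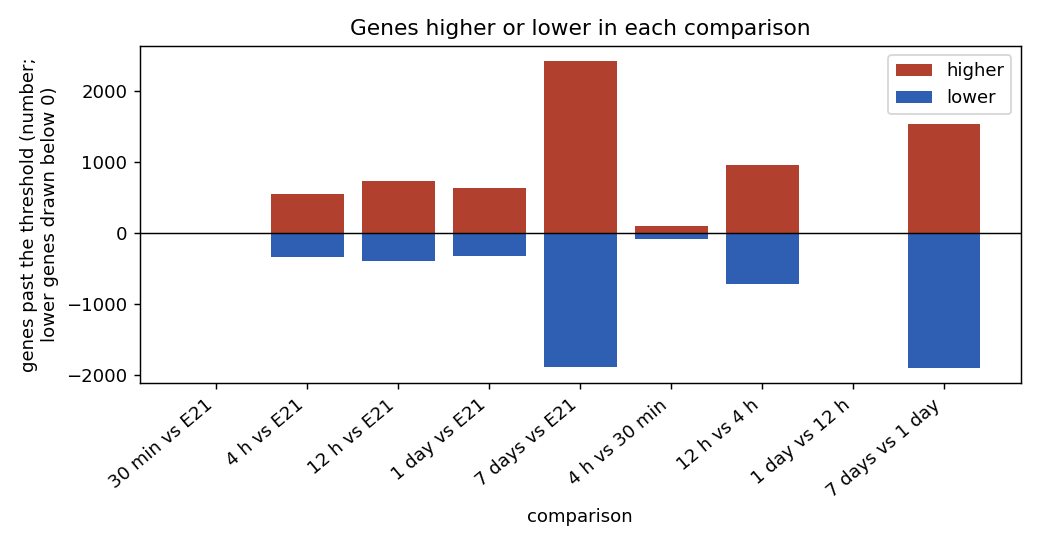
Genes higher and lower (number past the adjusted threshold of 0.05, bars from 0) in each of the 9 comparisons. No gene passed between E21 and 30 min, and the most, 4314, between E21 and 7 days.

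The comparison of 30 min with E21 covers the first minutes of life outside the uterus. Immediate early genes are transcription factors and signalling genes that respond to stimuli within minutes. Although no single gene passed in limma, the 30 of them had a median log2 change of 0.69 and were upward against other genes (adjusted p = 1.0e-19, and adjusted p = 0.119 with an estimated correlation). None of the 30 passed over all genes, and 17 were higher and 0 lower adjusted over the list alone. Among the larger differences, in genes chosen after their values were seen, were Jun at 3.43 ± 0.88, Dusp1 at 2.80 ± 0.62, Ccn1 at 2.55 ± 0.52 and Junb at 1.69 ± 0.33 (adjusted p = 0.323, 0.302, 0.284 and 0.256). The 3 arrays of 30 min did not contribute alike: the list median relative to the E21 mean was 0.30, 0.52 and 1.38, and Fos, also chosen after its values were seen, read 5.0, 5.33 and 8.38.

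Of the 34 lists, 19 passed at 30 min, 14 upward and 5 downward, and none held with an estimated correlation or in fry. Upward with the immediate early genes moved the hypoxia response (19 members, median 0.54, adjusted p = 1.1e-11, 7 higher over the list alone) and acute phase proteins (18, 0.56, 1.3e-09, 9 higher over the list alone). So did glycolysis (18, 0.28, 0.000123, 3 higher over the list alone) and glucocorticoid-induced genes (14, 0.49, 0.000123, 2 higher over the list alone). The adjusted p with an estimated correlation was 0.119, 0.119, 0.419 and 0.419 for these. Examples chosen after their values were seen are Egln3, an oxygen sensor, at 2.15 ± 0.48, Steap4 at 1.31 ± 0.29, and Socs3, a feedback inhibitor of cytokine signalling, at 1.27 ± 0.31, none past the threshold. Ribosome biogenesis (27 members, median 0.28, 3.75e-06) and lipogenesis (17, 0.69, 9.2e-05) were also upward, with adjusted p = 0.48 and 0.448 with an estimated correlation and no member past even over the list alone.

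Downward at 30 min were fatty acid oxidation and ketogenesis (21 members, median −0.54, adjusted p = 4.9e-10) and PPAR alpha targets (15, −0.68, 0.000797). The same held for B cell markers (10, −0.23, 0.0018), amino acid catabolism (24, −0.22, 0.0136) and platelet markers (10, −0.37, 0.0136). No member of these 5 passed by either adjustment, and with an estimated correlation the adjusted p was 0.419 for the first 3 and 0.518 for the other 2. Small upward shifts were called in endothelial (median 0.24, 0.000527), macrophage (0.20, 0.0292) and stellate markers (0.15, 0.0331). Others were in the unfolded protein and ATF4 response (0.18, 0.0115), cytochromes P450 (0.14, 0.016), cholesterol synthesis (0.24, 0.0174) and the growth hormone axis (0.18, 0.0331). With an estimated correlation the adjusted p lay between 0.419 and 0.655 for these 7.

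At 30 min limma passed 0 genes, with 1392 at an unadjusted p under 0.05 where 946.3 would be expected by chance. Array weights passed 15 genes and a trended and robust prior 0. The ages did not overlap in 2593 genes, 13.7%, where chance gives 10%. Without E21 replicate 1 the count was 8, and without it, 30 min replicate 3 and 4 h replicate 3 it was 3 (Itih5 −0.99, Pdia5 −2.49 and Peg10 3.49). Leaving out single arrays ended 9 of the 19 list calls. These were lipogenesis, cholesterol synthesis and amino acid catabolism without E21 replicate 1 or 30 min replicate 2 (highest adjusted p = 0.234, 0.477 and 0.666). Cytochromes P450 were lost without E21 replicate 2 or 30 min replicate 2 (0.786), and the ATF4 response without E21 replicate 1 (0.251). The platelet call ended without E21 replicate 1, 30 min replicate 1 or 30 min replicate 2 (0.998), and the macrophage call without E21 replicate 1, E21 replicate 2 or 30 min replicate 1 (0.111). The stellate call ended without E21 replicates 2 or 3 or 30 min replicates 1 or 2 (0.15), and the growth hormone call without E21 replicates 2 or 3 or 30 min replicates 2 or 3 (0.287). Without 1 array the medians of these lists ranged from 0.25 to 1.40 (lipogenesis), −0.10 to 0.74 (cholesterol synthesis), −0.47 to −0.16 (amino acid catabolism), −0.11 to 0.47 (cytochromes P450) and 0.05 to 0.24 (ATF4 response). For the others they ranged from −0.86 to −0.05 (platelets), 0.09 to 0.29 (macrophages), 0.06 to 0.27 (stellate cells) and 0.10 to 0.36 (growth hormone axis). Of the lists that kept their call, immediate early and glucocorticoid-induced genes came to 0.46 and 0.31 without 30 min replicate 3 and PPAR alpha targets to −0.38 without E21 replicate 3. Without E21 replicate 2 endothelial markers came to 0.13, acute phase proteins to 0.34 and ribosome biogenesis to 0.14. Glycolysis was 0.12, 0.14 and 0.57 without 30 min replicates 1, 2 and 3 and 0.48 without E21 replicate 3.

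By 4 h after birth, 892 genes differed from E21, 550 higher and 342 lower. Coq10b (transcript cluster TC0900000665.rn.1), which binds coenzyme Q, rose by 5.61 ± 0.54, 48.9-fold (adjusted p = 0.000134). Retreg1, a receptor for autophagy of the endoplasmic reticulum, rose by 4.80 ± 0.66 (0.00136), and Ppargc1a, a coactivator of genes of mitochondria and of glucose production, by 3.32 ± 0.57 (0.00446). Pdia5, a protein disulfide isomerase, fell by 2.58 ± 0.45 (0.00466, at least 2.17) and Anks4b fell by 2.34 ± 0.43 (0.00677, at least 1.15).

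Immediate early genes were still above E21 at 4 h (30 members, median 0.76, adjusted p = 3.9e-10, and adjusted p = 0.278 with an estimated correlation). Among them 10 were higher, 0 lower and 20 not past, and 12 were higher adjusted over the list alone. Gadd45b rose by 3.36 ± 0.55. Glucocorticoid-induced genes moved up (14 members, median 1.22, 4.35e-06, adjusted p = 0.278 with an estimated correlation), with 3 higher, 11 not past and 7 higher over the list alone. Sgk1, a kinase induced by glucocorticoids, rose by 2.43 ± 0.29 and Klf9 by 1.67 ± 0.36. Ribosome biogenesis was upward (27 members, median 0.52, 9.3e-11, adjusted p = 0.341 with an estimated correlation). It held 4 higher members, Wdr43 (1.40 ± 0.30) and Rrn3 (1.21 ± 0.21) among them, and 12 higher over the list alone. In the circadian clock list (17 members, median 0.35, 0.0029, adjusted p = 0.278 with an estimated correlation) 4 members were higher and 5 over the list alone. They included the repressor Nr1d2 (2.24 ± 0.33) and Rora (1.71 ± 0.33).

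Fatty acid oxidation and ketogenesis was lower at 4 h (21 members, median −0.62, adjusted p = 5.2e-09, and adjusted p = 0.291 with an estimated correlation). In it 0 members were higher, 4 lower and 17 not past, with 12 lower over the list alone. Eci1 and Decr1, enzymes of unsaturated fatty acid breakdown, were −1.42 ± 0.33 and −1.30 ± 0.33. Glycogen metabolism was lower too (11 members, median −0.53, 0.00237, adjusted p = 0.278 with an estimated correlation), with 2 lower, 9 not past and 4 lower over the list alone. Ppp1r3b, which targets a phosphatase to glycogen, was −2.19 ± 0.57 and Phkb, a phosphorylase kinase subunit, −0.81 ± 0.13. PPAR alpha targets did not pass as a list (0.0846), with 1 member lower, and with 3 lower and 1 higher over the list alone. That member, Vnn1, was −1.64 ± 0.45. Gluconeogenesis did not pass (0.165) although Ppargc1a, 1 of its 12 members, rose and 3 were higher over the list alone.

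The hypoxia response was upward at 4 h (19 members, median 0.66, adjusted p = 1.36e-05), with 2 higher, 17 not past and 6 higher over the list alone. Among them was Pfkfb3, a glycolytic regulator, at 1.64 ± 0.17 (at least 1.32). Acute phase proteins were upward (18, median 0.46, 2.19e-05), with 3 higher, 15 not past and 6 higher over the list alone. Steap4 (1.56 ± 0.29) and Socs3 (1.39 ± 0.31, at least 0.38) were among them. Stellate (16, 0.55, 2.67e-05), endothelial (15, 0.34, 0.000189) and macrophage markers (16, 0.37, 0.00779) had 2, 2 and 1 higher members, and 3, 7 and 2 over the list alone. Timp1 (1.06 ± 0.22), Lyve1 (1.09 ± 0.24) and C1qc (0.70 ± 0.18) are examples. The ATF4 response (23, 0.31, 0.00195) and glycolysis (18, 0.28, 0.0302) had 1 higher member each, and 5 and 1 over the list alone. Platelet (10, −0.70, 0.00049) and erythroid markers (22, −0.36, 0.00294) were downward, with 0 and 1 lower members and 1 each over the list alone. The adjusted p with an estimated correlation lay between 0.278 and 0.725 for these 9 lists. Outside the lists that passed, Cyp2c22 (2.80 ± 0.44), the cytochrome P450 reductase Por (2.52 ± 0.41), the cholesterol carrier Stard4 (2.21 ± 0.31) and the canalicular transporter Abcc2 (2.12 ± 0.42) rose.

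The 4 h arrays were uneven. Replicate 3 read Sik1 at 10.91 where the other 2 read 16.01 and 15.88, and Peg10 at 7.30 against 13.91 and 12.77. Its erythroid median was −1.04 relative to E21. It was also nearer to E21 in fatty acid oxidation (−0.14 against −1.18 and −0.78) and in the hypoxia response (0.11 against 1.00 and 0.68). The limma count of 892 went to 1371 without 4 h replicate 3, 274 and 335 without 4 h replicates 2 and 1, and 299 and 505 without E21 replicates 2 and 3. In all, 15 of 40 calls of named genes held in all 6 leave-one-out fits. Chac1 (4.88 ± 1.28, at least 2.71), Peg10 (4.77 ± 1.14, at least 4.61), Nr4a2 (2.14 ± 0.57, at least 1.41, and 1.35 without 4 h replicate 2), Eci1, Decr1, Vnn1, C1qc and Kmo (−1.78 ± 0.41) passed only in the fit without 4 h replicate 3 (highest adjusted p = 0.203, 0.137, 0.198, 0.126, 0.167, 0.23, 0.195 and 0.123). Sik1 (4.68 ± 1.08; 0.126), Ppp1r3b (0.166), Klf9 (0.0891) and Socs3 (0.112) lost the call without E21 replicates 2 or 3 or 4 h replicates 1 or 2. Lyve1 (0.0989) lost it without E21 replicates 1 or 2 or 4 h replicates 1 or 2, and Wdr43 (0.0959) without E21 replicate 2 or 4 h replicates 1 or 2. Timp1 (0.0741) and Rora (0.0544) lost it without 4 h replicates 1 or 2, and Abcc2 (0.0656) without E21 replicate 2 or 4 h replicate 2.

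Of the list calls at 4 h, glycolysis was lost without E21 replicates 1 or 2 or 4 h replicates 1 or 2 (highest adjusted p = 0.148), erythroid markers without E21 replicate 2 or 4 h replicate 3 (0.66), and macrophage markers without 4 h replicate 2 (0.0766). Without 1 array the medians of these 3 ranged from 0.13 to 0.45, −0.62 to −0.07 and 0.32 to 0.56. Of the other lists, glycogen metabolism came to −0.27 without E21 replicate 3, the hypoxia response to 0.34 without 4 h replicate 1, and the circadian clock to 0.15 and 0.19 without E21 replicate 2 and 4 h replicate 3. Acute phase proteins came to 0.70 and the ATF4 response to 0.20 without E21 replicate 1, and fatty acid oxidation to −0.95 without 4 h replicate 3. Without E21 replicate 1, 30 min replicate 3 and 4 h replicate 3 together 1467 genes passed at 4 h, 715 of them shared with the 892. In that fit gluconeogenesis passed upward (median 1.34, 0.00647), PPAR alpha targets downward (−0.78, 0.0177), and the erythroid list did not pass (−0.07, 0.92).

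At 12 h 1124 genes differed from E21, 731 higher and 393 lower. Inhbe (TC0700002919.rn.1), the subunit of the hepatokine activin E, rose by 8.16 ± 1.00, 286-fold (adjusted p = 0.000227). Plin2, which coats lipid droplets, rose by 6.22 ± 0.53 (6.1e-06), the thioesterase Acot1 by 5.73 ± 0.47 (5.4e-06), and Cpt1a, the rate-limiting carnitine palmitoyltransferase of fatty acid entry into mitochondria, by 3.07 ± 0.49 (0.00162). Insig1 (TC0400000004.rn.1), which holds back the cleavage of SREBP, fell by 5.69 ± 0.52 (1.6e-05), and Hdc, the enzyme that makes histamine, fell by 5.49 ± 0.83 (0.00108).

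PPAR alpha targets were higher at 12 h (15 members, median 1.15, adjusted p = 1.84e-07, and adjusted p = 0.325 with an estimated correlation), with 5 higher, 10 not past and 7 higher over the list alone. Fatty acid oxidation and ketogenesis was higher as well (21 members, median 0.36, 0.00664, adjusted p = 0.897 with an estimated correlation), with 4 higher, 17 not past and 6 higher over the list alone. Cholesterol synthesis fell (20 members, median −1.59, 2.4e-16, adjusted p = 0.325 with an estimated correlation). Of its members 12 were lower, 8 not past and 0 higher, and 15 were lower over the list alone, with Insig1 and Msmo1 (−4.01 ± 0.63) the largest. Lipogenesis was lower (17 members, median −0.91, 0.014, adjusted p = 0.897 with an estimated correlation), with 5 lower, 1 higher, 11 not past and 7 lower over the list alone. Its member Elovl5, an elongase, rose by 2.68 ± 0.34. The desaturase Scd2, outside the list, fell by 5.45 ± 0.60. Acot1 and Acot2, and Scd and Scd2, are close paralogs, and cross-hybridization between them was not tested.

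Glycogen metabolism was lower at 12 h (11 members, median −0.99, adjusted p = 4.76e-05, and adjusted p = 0.183 with an estimated correlation), with 4 lower, 7 not past and 7 lower over the list alone. Ugp2, which makes UDP-glucose, fell by 1.82 ± 0.34. Amino acid catabolism was lower (24 members, median −0.73, 0.000253), with 6 lower, 18 not past, and 7 lower and 2 higher over the list alone, including Kmo (−2.80 ± 0.41). Its median was −0.33 without E21 replicate 1 and −0.48 without 12 h replicate 1, and that of glycogen metabolism −1.50 and −0.64 without E21 replicates 1 and 3. Platelet markers were lower (10 members, median −0.63, 0.000275) with 0 past and 2 lower over the list alone. Amino acid catabolism and platelet markers had adjusted p = 0.897 with an estimated correlation. The circadian clock list did not pass but held 5 higher and 3 lower members, Nr1d1 at 2.76 ± 0.32 (at least 1.88) and Per1 at −1.87 ± 0.35. Por rose by 3.00 ± 0.41 among 4 higher and 2 lower genes of the cytochrome P450 list, which did not pass. Outside that list the cytochrome P450 Cyp3a23-3a1 rose by 5.55 ± 0.85. Slc34a2, a sodium-phosphate transporter, rose by 6.46 ± 0.61, Pfkfb1 fell by 3.23 ± 0.38 and Hif3a fell by 4.48 ± 0.48.

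The count of 1124 at 12 h fell to 620 and 672 without 12 h replicates 1 and 2 and to 635 without E21 replicate 2. Of 44 calls of named genes 29 held in all 6 leave-one-out fits. The lipogenesis call was lost without E21 replicate 3 or 12 h replicate 3 (highest adjusted p = 0.516), with a median of −0.38 in the first of these fits. Its E21 arrays lay at −0.91, −0.18 and 1.08 around their mean. Fasn, fatty acid synthase, was −3.58 ± 0.91 (0.0302) with a call that held only without E21 replicate 1 (highest adjusted p = 0.117).

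At 1 day 961 genes differed from E21, 638 higher and 323 lower, and 486 higher and 403 lower after quantile normalization again. Inhbe rose by 8.43 ± 1.00, 345-fold (adjusted p = 0.00027), the lipase Abhd2 (TC0100001826.rn.1) by 4.91 ± 0.28 (3.9e-07), and Cpt1a by 2.80 ± 0.49 (0.00445). Hdc (TC0300004087.rn.1) fell by 11.02 ± 0.83 (5.0e-06), from 18.68 ± 1.27 to 7.66 ± 0.25 (SD, n = 3). The phosphatidate phosphatase Lpin1 fell by 4.55 ± 0.44 (5.6e-05) and Rbp2, a retinol-binding protein, fell by 5.33 ± 0.74 (0.000829).

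Fatty acid oxidation and ketogenesis was higher at 1 day (21 members, median 0.69, adjusted p = 1.29e-06, and adjusted p = 0.481 with an estimated correlation), with 7 higher, 14 not past and 11 higher over the list alone. Eci1 rose by 2.04 ± 0.33. PPAR alpha targets were higher (15 members, median 0.82, 3.09e-07, adjusted p = 0.276 with an estimated correlation), with 5 higher, 10 not past and 6 higher over the list alone. The PPAR median was 1.85, 0.46 and 0.41 in the 3 arrays, and 0.34 without replicate 1. Cholesterol synthesis was lower (20 members, median −1.83, 4.5e-19, adjusted p = 0.186 with an estimated correlation): 14 were lower, 6 not past and 17 lower over the list alone. Lipogenesis was lower (17 members, median −0.89, 8.5e-05, adjusted p = 0.499 with an estimated correlation), with 5 lower, 1 higher, 11 not past and 8 lower over the list alone. Its member Scd fell by 5.11 ± 1.01, and Scd2, outside the list, fell by 6.38 ± 0.60.

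Cell cycle genes were higher at 1 day (42 members, median 0.58, adjusted p = 4.0e-12, and adjusted p = 0.485 with an estimated correlation), with 3 higher, 39 not past and 23 higher over the list alone. The list medians were 0.55, 0.59 and 0.61 in the 3 arrays. Cdk1, the kinase that drives mitosis, was 0.78 ± 0.19 (0.0282) and Ccne1, cyclin E, 0.88 ± 0.22 (0.0324). Fetal and imprinted growth genes were lower (16 members, median −0.19, 0.0165, adjusted p = 0.186 with an estimated correlation), with 3 lower, 1 higher, 12 not past and 4 lower over the list alone. The imprinted cell cycle inhibitor Cdkn1c fell by 3.94 ± 0.56 and Dlk1 fell by 2.90 ± 0.50.

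Glycogen metabolism was lower at 1 day (11 members, median −0.57, adjusted p = 0.000324, and adjusted p = 0.186 with an estimated correlation), with 5 lower, 6 not past and 6 lower over the list alone. Pygl, liver glycogen phosphorylase, fell by 1.90 ± 0.26. Amino acid catabolism was lower (24 members, median −0.59, 5.5e-05) with 6 lower, 18 not past and 8 lower over the list alone. Fah (−1.79 ± 0.23) was among them. The urea cycle (9, −0.76, 0.0214) had 1 lower member, Otc (−1.83 ± 0.35), by both adjustments. The hypoxia response (19, −0.39, 0.00352) had 2 lower, 1 higher and 5 lower over the list alone, with Bnip3 at −2.16 ± 0.42. The hypoxia median was −0.16 without E21 replicate 3 and −0.17 without 1 day replicate 2. Amino acid catabolism came to −0.39 and −0.38 without E21 replicate 1 and 1 day replicate 3, and glycogen metabolism to −1.12 without 1 day replicate 3. Platelet (10, −0.93, 1.14e-06), neutrophil (15, −0.49, 0.0165) and B cell markers (10, −0.20, 0.0343) were lower with 0 members past, and 7 platelet genes lower over the list alone. The median level of the B cell list lay below 6.72 on every array. Cytochromes P450 were higher (29, 0.57, 0.0343), with 4 higher, 1 lower, and 7 higher and 2 lower over the list alone, Por at 2.60 ± 0.41 among them. With an estimated correlation the adjusted p lay between 0.468 and 0.716 for these 7 lists. Of the 12 gluconeogenesis genes Fbp1 rose by 1.5 ± 0.21, and the list, which did not pass, had a median of −0.14 and a mean of 0.29.

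The count of 961 at 1 day fell to 425 and 616 without E21 replicates 2 and 3 and to 583 and 637 without 1 day replicates 1 and 3. Of 46 calls of named genes 29 held in all 6 leave-one-out fits. Cdk1 and Ccne1 lost their calls without E21 replicates 2 or 3 (highest adjusted p = 0.109 and 0.153), Cdk1 also without 1 day replicates 1 or 3 and Ccne1 without 1 day replicates 2 or 3. List calls were lost for the urea cycle without E21 replicate 1 or 1 day replicate 3 (0.181), cytochromes P450 without E21 replicate 2, 1 day replicate 1 or 1 day replicate 3 (0.67), and fetal genes without 1 day replicate 2 (0.0749). Those of neutrophil markers were lost without E21 replicates 1 or 2 or 1 day replicate 3 (0.19), and those of B cells without E21 replicates 1 or 2 or 1 day replicates 2 or 3 (0.172). The urea cycle median came to −0.49 without E21 replicate 1, and that of neutrophils to −0.88 and −0.28 without E21 replicate 3 and 1 day replicate 3. That of cytochromes P450 came to 0.04, 0.37 and 0.36 without E21 replicate 2 and 1 day replicates 1 and 3. Trib3, a target of ATF4 chosen after its values were seen, read 12.54 in 1 day replicate 3 and 7.39 and 7.11 in the other arrays.

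**Figure D2:**
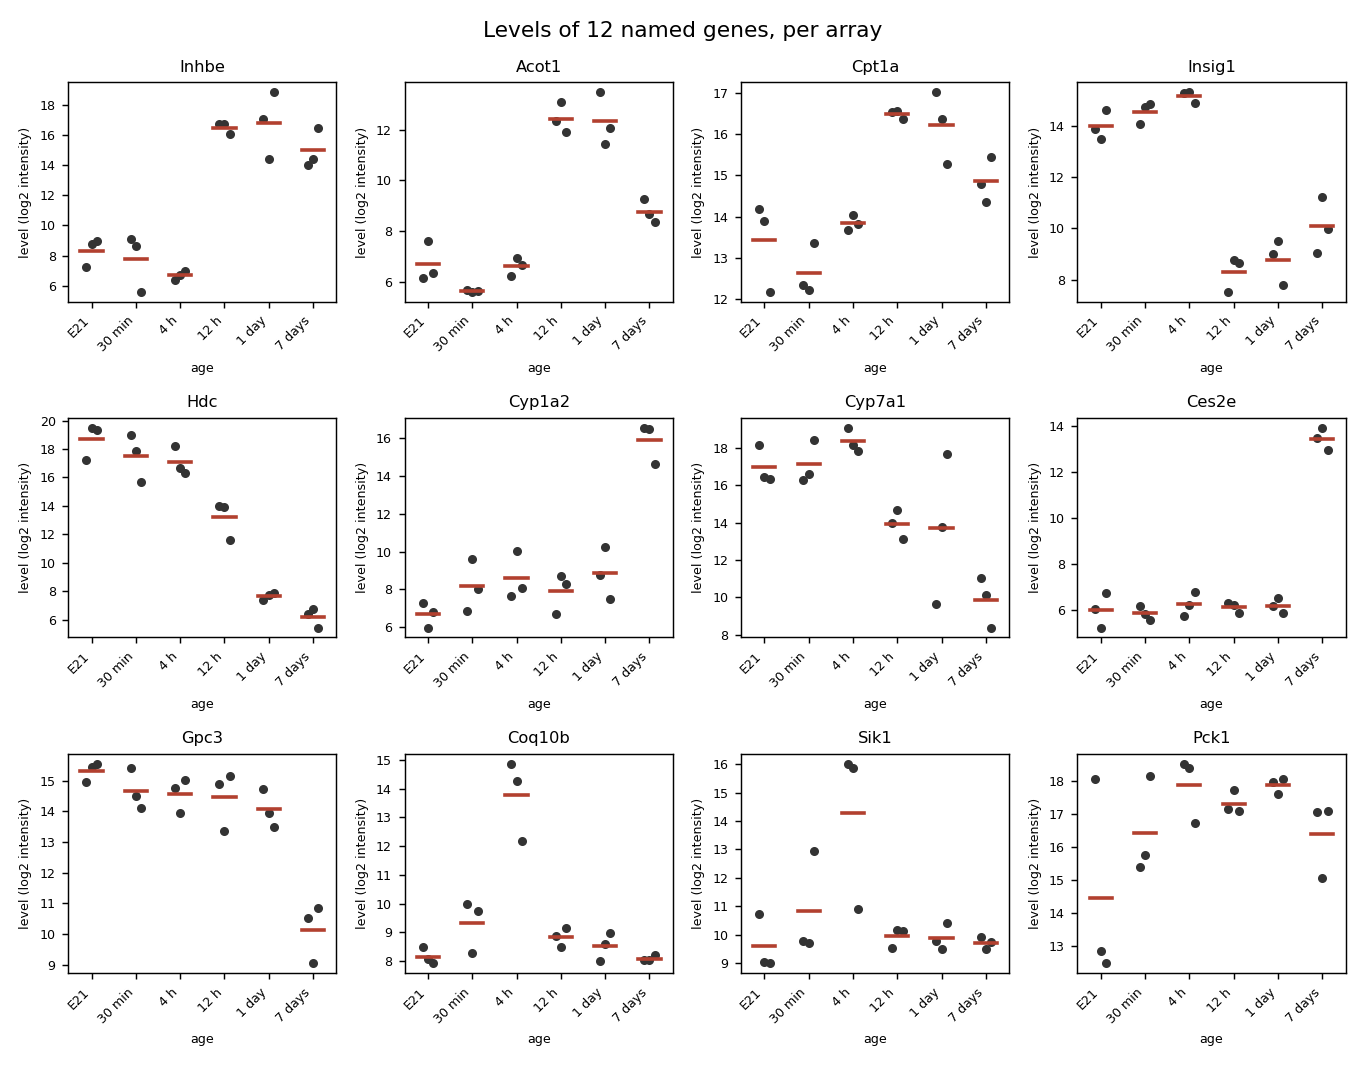
Log2 intensity of 12 genes on each array, by age, with bars at the mean of the 3 arrays and replicates 1 to 3 from left to right. Inhbe, Acot1 and Cpt1a read higher at 12 h than at E21, Insig1 lower, Cyp1a2 and Ces2e higher and Gpc3 and Cyp7a1 lower at 7 days, while Pck1 read 18.06 in E21 replicate 1 and 12.87 and 12.48 in the other E21 arrays.

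At 7 days the liver differed from E21 in 4314 genes, 22.8% of those tested, with 2422 higher and 1892 lower. Cyp1a2 (TC0800002637.rn.1), a drug-metabolizing cytochrome P450, rose by 9.20 ± 0.85, at least 495-fold (adjusted p = 2.8e-06), and the carboxylesterase Ces2e (TC1900000003.rn.1) by 7.48 ± 0.35 (1.8e-08, at least 6.73). Hdc fell by 12.50 ± 0.83 (2.6e-07, at least 11.96) and Gpc3 (TC0X00002490.rn.1), a fetal liver proteoglycan, by 5.19 ± 0.53 (5.9e-06). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 7.14 ± 1.38 (0.00146) and Cyp8b1, which acts in the cholic acid branch, fell by 4.65 ± 0.73 (0.000294).

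Erythroid, platelet and neutrophil markers fell at 7 days. Of 22 erythroid genes 21 were lower, 1 not past and 21 lower over the list alone (median −4.38, adjusted p = 5.4e-28, and adjusted p = 0.0984 with an estimated correlation). Examples are Ermap at −5.33 ± 0.40 and Rhag, of the Rh complex, at −4.97 ± 0.45. All 10 platelet and megakaryocyte genes were lower by both adjustments (median −3.17, 1.67e-14, adjusted p = 0.115 with an estimated correlation). The platelet chemokines Ppbp (TC1400001509.rn.1) and Pf4 were −6.63 ± 0.56 (at least 6.28 lower) and −5.66 ± 0.44. Of 15 neutrophil genes 10 were lower, 5 not past and 11 lower over the list alone (median −2.57, 1.31e-09, adjusted p = 0.265 with an estimated correlation). Examples are the granule proteins Mpo at −5.24 ± 0.39 and Elane at −4.41 ± 0.43.

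Cell cycle genes fell together with them (42 members, median −1.09, adjusted p = 2.26e-14, and adjusted p = 0.386 with an estimated correlation). Of them 29 were lower, 13 not past, 0 higher and 32 lower over the list alone, and the proliferation marker Mki67 fell by 2.37 ± 0.28. Ribosome biogenesis was lower (27 members, median −0.67, 7.63e-08, adjusted p = 0.386 with an estimated correlation), with 13 lower, 14 not past and 15 lower over the list alone, among them Npm1 (−1.59 ± 0.22). Fetal and imprinted growth genes fell (16 members, median −0.54, 2e-04, adjusted p = 0.0611 with an estimated correlation), with 7 lower, 1 higher, 8 not past and 8 lower over the list alone, Dlk1 at −4.78 ± 0.50.

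Macrophage and endothelial markers rose. The rise of stellate markers lay mostly on 7 days replicates 2 and 3, with medians of 0.19, 1.07 and 1.55 relative to E21 in replicates 1 to 3. Of 16 macrophage genes 12 were higher, 1 lower, 3 not past and 13 higher over the list alone (median 1.34, adjusted p = 2.75e-06, and adjusted p = 0.265 with an estimated correlation). The Kupffer cell genes Cd5l and Vsig4 were 4.64 ± 0.61 and 3.86 ± 0.39. Of 15 endothelial genes 11 were higher, 1 lower, 3 not past and 13 higher over the list alone (median 1.19, 5.38e-06, adjusted p = 0.292 with an estimated correlation). Fcgr2b was 2.68 ± 0.32 and Eng 1.66 ± 0.20. Of 16 stellate genes 7 were higher, 9 not past and 9 higher over the list alone (median 0.99, 7.4e-06, adjusted p = 0.292 with an estimated correlation). Pdgfrb was 2.72 ± 0.23 and Hgf 2.41 ± 0.24.

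Cytochromes P450 and plasma proteins rose as well. Of 29 cytochrome P450 and conjugation genes 11 were higher, 1 lower, 17 not past and 12 higher over the list alone (median 0.98, adjusted p = 0.000367, and adjusted p = 0.386 with an estimated correlation), and the median was 0.52 without E21 replicate 2. Plasma proteins had 13 higher, 1 lower and 15 not past of 29, and 15 higher over the list alone (median 0.34, 4.46e-05, adjusted p = 0.386 with an estimated correlation). Complement C9 was 3.42 ± 0.45 and Apoa2 −3.80 ± 0.47. Fatty acid oxidation (21 members, median 0.44, 0.0276) and PPAR alpha targets (15, 0.78, 0.0353) had 8 and 6 higher members and 1 and 0 lower, and 9 and 8 higher over the list alone. Hadh, an enzyme of beta oxidation, rose by 1.85 ± 0.24. Glycolysis was lower (18, −0.49, 0.000363), with 6 lower, 1 higher and 7 lower over the list alone, Hk1 at −3.11 ± 0.28. The hypoxia response (19, −0.36, 0.0353) had 5 lower and 2 higher members, Egln3 at −3.14 ± 0.48 (at least 2.30 lower). Glycogen metabolism (11, −0.58, 0.042) had 4 lower and 1 higher, Gbe1 at −1.97 ± 0.47. Over the list alone 6 hypoxia and 5 glycogen genes were lower. The adjusted p with an estimated correlation lay between 0.386 and 0.644 for these 5 lists.

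The pancreas list passed at 7 days (11 members, median 2.31, adjusted p = 0.0361, and adjusted p = 0.644 with an estimated correlation) with 1 higher member, Cpb1 (4.14 ± 1.12, at least 2.21), and the skeletal muscle list did not (10 members, median 1.13, 0.0594). The median of each rested on 1 array. The pancreas medians relative to E21 were −0.03, −0.12 and 6.88 in replicates 1 to 3, and the muscle medians −0.07, 3.54 and −0.08. Acta1, skeletal actin, was 2.21 ± 1.26 (0.256), at 13.78 in replicate 2 and 6.34 and 6.69 in the others. Ctrb1, chymotrypsinogen, chosen after its values were seen, read 17.80 in replicate 3 and 5.59 and 5.25 in the others. Without 7 days replicate 3 the pancreas median was −0.08 (0.749), and without replicate 2 it was 3.48. Cpb1 read 13.21 in replicate 3 and 7.15 and 6.43 in replicates 1 and 2, where the 15 arrays of earlier ages read 4.45 to 5.04. Its call held in all 6 leave-one-out fits, at 2.00 without replicate 3. Erythroid medians were −3.74, −4.81 and −4.41 and macrophage medians 1.15, 1.63 and 1.18 in replicates 1 to 3. The stellate medians were 0.19, 1.07 and 1.55, so the stellate rise was mostly on the 2 arrays with high muscle or pancreas genes, and without both of these its median was 0.19 (0.0151).

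**Figure D3:**
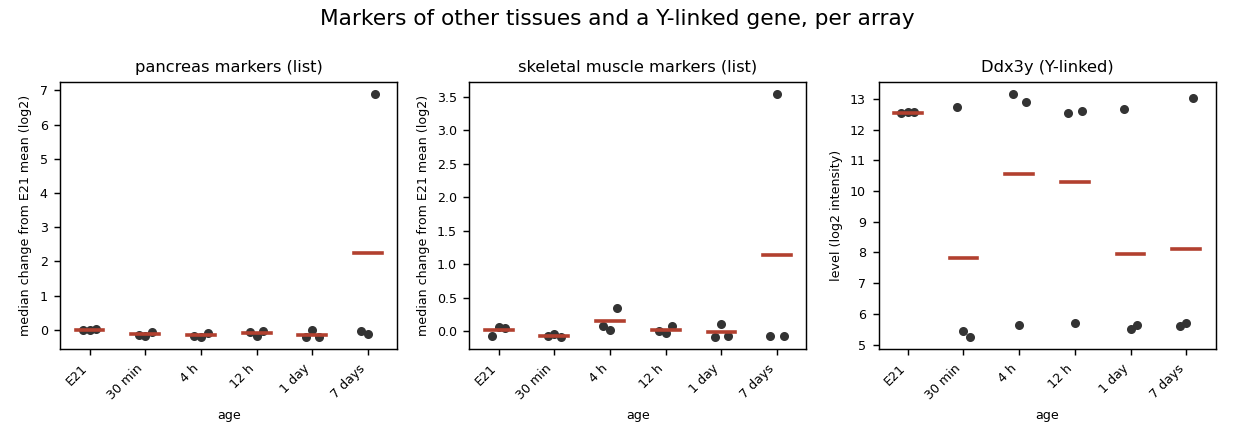
Median log2 difference from the E21 mean of the pancreas and skeletal muscle lists, and log2 intensity of the Y-linked gene Ddx3y, on each of the 18 arrays, with replicates 1 to 3 of an age from left to right. The pancreas list lies at 6.88 in 7 days replicate 3 and the muscle list at 3.54 in 7 days replicate 2.

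The other lists did not pass at 7 days. Adjusted p was 0.165 for gluconeogenesis (1 higher, 4 lower, with G6pc1 at −2.45 ± 0.79), 0.527 for lipogenesis (1 higher, 3 lower, with Scd at −4.93 ± 1.01 and Elovl5 at 3.17 ± 0.34) and 0.544 for cholesterol synthesis (1 higher, 1 lower, Insig1 at −3.91 ± 0.52). For bile acids it was 0.248 (4 higher, 3 lower) and for the urea cycle 0.201 (2 lower, Ass1 at −2.86 ± 0.59). It was 0.201 for amino acid catabolism (4 higher, 6 lower), 0.614 for immediate early genes (5 higher, 2 lower, Myc at −1.95 ± 0.44) and 0.459 for acute phase proteins (6 higher, 2 lower, Steap4 at 2.84 ± 0.29 and Orm1 at −4.88 ± 0.73). Of the stress lists, 0.501 was that of heat shock proteins (1 higher, 2 lower, Hsp90aa1 at −1.43 ± 0.27) and 0.265 that of the ATF4 response (4 higher, 2 lower). It was 0.12 for the circadian clock (7 higher, 1 lower, Per3 at 2.08 ± 0.28 and Per1 at −1.71 ± 0.35) and 0.249 for glucocorticoid-induced genes (1 higher, 3 lower). It was 0.165 for the growth hormone and IGF axis (5 higher, 2 lower, Igfals at 3.82 ± 0.65 and Igfbp4 at 3.83 ± 0.74). Among cell markers it was 0.0677 for B cells (2 lower), 0.248 for T and NK cells (4 higher, 1 lower, Cd4 at 2.81 ± 0.36 and Nkg7 at −3.13 ± 0.38) and 0.513 for the 7 cholangiocyte genes (2 higher, Sox9 at 0.71 ± 0.22).

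Leaving out 7 days replicates 2 and 3 together leaves 1 array at 7 days, which limma assumes to vary like the arrays of other ages. In that fit 1807 genes passed, 1739 of them shared with the 4314, all in the same direction. Of 72 calls of named genes 59 held in all 6 leave-one-out fits. G6pc1 (highest adjusted p = 0.187) lost its call without E21 replicates 1 or 2 or 7 days replicates 2 or 3, Sox9 (0.142) without E21 replicates 1 or 2 or 7 days replicates 2 or 3. Lists lost were fatty acid oxidation without E21 replicate 2 or 7 days replicate 1 (0.158, with medians of 0.28 and 0.25), PPAR alpha targets without 7 days replicate 1 (0.0702), and hypoxia without E21 replicate 3 or 7 days replicate 1 (0.112). Glycogen was lost without E21 replicates 2 or 3 or 7 days replicate 2 (0.11), and pancreas without E21 replicate 3 or 7 days replicate 3 (0.749).

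**Figure D4:**
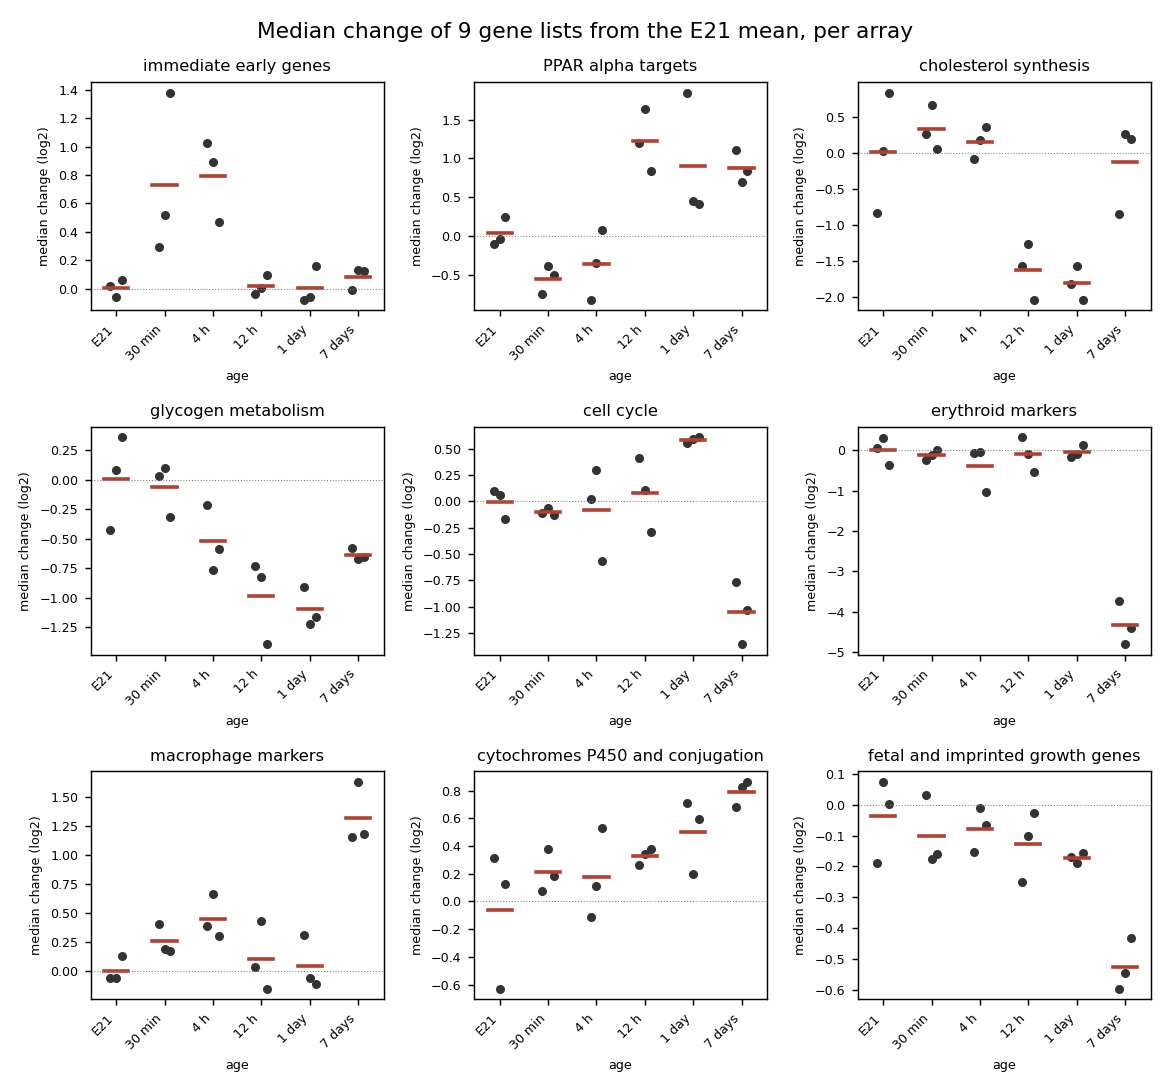
Median log2 difference from the E21 mean over the measured members of 9 gene lists, on each array, with bars at the mean of the 3 arrays of an age. Cholesterol synthesis lies between −2.04 and −1.26 on the 6 arrays of 12 h and 1 day, and erythroid markers between −4.81 and −3.74 at 7 days.

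From 30 min to 4 h 186 genes passed, 98 higher and 88 lower. Coq10b rose by 4.44 ± 0.54 (adjusted p = 0.00187) and Retreg1 by 4.16 ± 0.66 (0.00815). Dcun1d2 fell by 1.60 ± 0.24 (0.00606, at least 1.29), C3ar1, a complement receptor, fell by 1.75 ± 0.29 (0.01), and Zfp36, which destabilizes cytokine mRNA, fell by 1.76 ± 0.36 (0.0303). Ribosome biogenesis (median 0.28, 0.000369), stellate (0.39, 0.0119) and B cell markers (0.28, 0.0196) were upward and glycogen metabolism (−0.17, 0.0229) and lipogenesis (−0.52, 0.0261) downward, with adjusted p = 0.954 with an estimated correlation for all 5. None of their members passed, and adjusted over the list alone 1 ribosome biogenesis and 1 B cell gene were higher and 2 glycogen genes lower.

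Between 30 min and 4 h the count was 438 without 4 h replicate 3, 62 and 63 without 4 h replicates 1 and 2, and 104 and 46 without 30 min replicates 1 and 2. All 5 list calls were lost without 4 h replicate 2 (highest adjusted p in any leave-one-out fit = 0.0545 for ribosome biogenesis and 0.596 for lipogenesis). Medians ranged without 1 array from −0.45 to −0.09 (glycogen), −0.77 to −0.15 (lipogenesis), 0.10 to 0.39 (B cells), 0.26 to 0.47 (stellate cells) and 0.20 to 0.45 (ribosome biogenesis). The ribosome biogenesis call was lost without 4 h replicate 2 alone, lipogenesis also without 30 min replicate 2 or 4 h replicate 1. Glycogen was lost also without 30 min replicates 1 or 2 (0.105), B cell markers also without 30 min replicate 1 (0.27) and stellate markers also without 30 min replicate 3 (0.102). The Zfp36 call was lost without 30 min replicates 2 or 3 or 4 h replicates 1 or 2 (0.144), Retreg1 without 30 min replicate 2 (0.0554) and C3ar1 without 4 h replicate 1 (0.057).

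From 4 h to 12 h 1684 genes passed, 961 higher and 723 lower, or 778 higher and 901 lower with array medians made equal. Inhbe rose by 9.81 ± 1.00, at least 830-fold (adjusted p = 2.8e-05), Slc34a2 by 6.70 ± 0.61 and Acot1 by 5.80 ± 0.47. Insig1 fell by 6.85 ± 0.52 (3.4e-06) and Scd2 fell by 6.08 ± 0.60. Cholesterol synthesis fell (median −1.72, 2.9e-16, 12 of 20 lower, 16 over the list alone), and fatty acid oxidation (1.06, 1.1e-13, 12 of 21 higher, 19 over the list alone) and PPAR alpha targets (2.09, 3.1e-11, 10 of 15 higher, 12 over the list alone) rose, with adjusted p = 0.214 with an estimated correlation for each. Of the 11 lists that had been up at 4 h 6 moved down. Among these were glucocorticoid-induced genes (−1.91, 1.3e-08, 8 of 14 lower and 1 higher), immediate early genes (−0.70, 1.66e-08, 10 of 30 lower), the hypoxia response (−0.87, 1.39e-07, 9 of 19 lower) and ribosome biogenesis (−0.43, 1.87e-08, 4 of 27 lower). Over the list alone 12, 13, 11 and 6 were lower. None of these list calls held with an estimated correlation.

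The other 2 lists that moved down after 4 h were endothelial (median −0.43, adjusted p = 0.000775, 1 of 15 lower) and stellate markers (−0.62, 0.00167, 2 of 16 lower and 1 higher). Also lower at 12 h than at 4 h were lipogenesis (−0.71, 0.00322, 5 of 17 lower and 1 higher) and amino acid catabolism (−0.43, 0.00887, 4 of 24 lower and 1 higher). With an estimated correlation the adjusted p lay between 0.214 and 0.655 for the lists that fell. The count was 956 and 1069 without 4 h replicates 1 and 2 and 883 without 12 h replicate 1. The stellate median was −0.41 without 4 h replicate 2 and the endothelial one −0.28 without 12 h replicate 3. Lipogenesis and amino acid catabolism were lost without 4 h replicate 3 (0.062 and 0.223), and Sds (−6.14 ± 1.83, 0.0488) lost its call without any 1 of the 6 arrays (highest adjusted p = 0.185) and with the replicate number of the 2 ages as a block (0.0642).

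From 12 h to 1 day 7 genes passed in limma, 2 higher and 5 lower (2 and 3 with array medians made equal), with 1213 at an unadjusted p under 0.05. Nr1d1, a repressor of the circadian clock, fell by 2.84 ± 0.32 (adjusted p = 0.00257, at least 1.88), Tgfa, a ligand of the epidermal growth factor receptor, fell by 1.20 ± 0.12 (0.00112), and Hdc fell by 5.53 ± 0.83 (0.0288). Egfr, that receptor, rose by 1.73 ± 0.25 (0.0223) and Cadps2 by 0.82 ± 0.12 (0.0223). Cell cycle genes moved up (42 members, median 0.53, 1.4e-21, adjusted p = 0.805 with an estimated correlation) with 0 past and 10 higher over the list alone. Fatty acid oxidation was upward (0.22, 0.00384, adjusted p = 0.987 with an estimated correlation) and fetal genes downward (−0.20, 0.0155, adjusted p = 0.27 with an estimated correlation), each with 0 past and 1 over the list alone.

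The count of 7 was 3 without 12 h replicate 1, 12 h replicate 2 or 1 day replicate 1, and 12 without 1 day replicate 2. Non-overlap was seen in 1804 genes, 9.53%, where chance gives 10%. Egfr (highest adjusted p = 0.149) lost its call without 12 h replicates 1 or 2 or 1 day replicates 1 or 3, Cadps2 (0.08) in all fits but that without 1 day replicate 2, and Hdc (0.149) in all but that without 12 h replicate 3. The fatty acid oxidation call was lost without 1 day replicate 1 (0.669), where its median was 0.11 against 0.38 without 1 day replicate 3, and that of fetal genes without 12 h replicate 2 or 1 day replicate 2 (0.176).

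From 1 day to 7 days 3441 genes passed, 1543 higher and 1898 lower. The glutathione transferase Gstp3 rose by 7.43 ± 0.79 (adjusted p = 1.7e-05), Ces2e by 7.28 ± 0.35 (at least 6.73) and Cyp1a2 by 7.05 ± 0.85. Ppbp fell by 5.59 ± 0.56 (at least 5.25), Ermap fell by 5.45 ± 0.40 and Orm1, an acute phase glycoprotein, fell by 5.49 ± 0.73. Cell cycle (median −1.66, 1.7e-31, 39 of 42 lower, 41 over the list alone), erythroid (−4.28, 3.1e-31, 21 of 22 lower) and platelet (−2.27, 7.6e-12, 9 of 10 lower) genes fell. So did neutrophil (−1.93, 2.04e-08, 8 of 15 lower) and ribosome biogenesis genes (−0.70, 6.3e-12, 19 of 27 lower, 24 over the list alone). Cholesterol synthesis rose again (1.47, 3.08e-10, 12 of 20 higher, 17 over the list alone). The adjusted p with an estimated correlation lay between 0.143 and 0.253 for these 6 lists.

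Also upward from 1 day to 7 days were stellate (median 1.16, adjusted p = 3.4e-07, 11 of 16 higher, and 0.59 without 7 days replicates 2 and 3), macrophage (1.07, 8.7e-07, 10 of 16 higher and 1 lower) and endothelial markers (0.77, 6.04e-06, 8 of 15 higher). So were plasma proteins (0.58, 3.4e-07, 15 of 29 higher and 1 lower), lipogenesis (0.72, 0.0179, 4 of 17 higher), the growth hormone axis (0.48, 0.0269, 5 of 16 higher) and cytochromes P450 (0.38, 0.0157, 2 of 29 higher and 1 lower). Downward were glycolysis (−0.43, 0.000522, 4 of 18 lower), fetal genes (−0.33, 0.0142, 5 of 16 lower) and PPAR alpha targets (−0.46, 0.0218, 3 of 15 lower). So were gluconeogenesis (−0.66, 0.0462, 1 of 12 lower) and heat shock proteins (−0.32, 0.0494, 5 of 10 lower). The pancreas (2.19, 0.00614, 2 of 11 higher) and muscle lists (1.09, 0.0299, 0 of 10 past) passed with 7 days replicates 3 and 2 in the comparison. With an estimated correlation the adjusted p lay between 0.173 and 0.608 for these 14 lists.

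The count of 3441 was 2276 without 7 days replicate 2, and 1006 without 7 days replicates 2 and 3, 954 of them shared, with 1 array left at 7 days. Calls were lost for the muscle list without 7 days replicate 2 or 1 day replicate 1 (median −0.04 at the lowest, highest adjusted p = 0.352), pancreas without 7 days replicate 3 (0.07, 0.268) and PPAR alpha targets without 1 day replicate 1 (0.03, 0.322). Their medians reached 1.70, 3.36 and −0.87 in other fits without 1 array. Lipogenesis was lost without 7 days replicate 2 (0.40, 0.0633), cytochromes P450 without 1 day replicate 2 or 7 days replicate 1 (0.0851) and the growth hormone axis without 1 day replicate 2 or 7 days replicate 3 (0.177). Gluconeogenesis was lost without 1 day replicates 1 or 2 or 7 days replicates 2 or 3 (0.132), and heat shock proteins without 1 day replicates 1 or 2 or 7 days replicates 1 or 3 (0.0936). The other 12 list calls held in all 6 leave-one-out fits.

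No gene was called higher at 30 min for a time only, since limma passed none at 30 min, where 1392 had an unadjusted p under 0.05. In 20 simulated sets of arrays with no difference between ages the mean and the highest count were 0, and array weights gave 2 genes. Groups did not overlap in 21.0%, 21.5%, 20.6% and 37.1% of genes at 4 h, 12 h, 1 day and 7 days against E21, where chance gives 10%. Arrays with Y-linked expression (Ddx3y above 9) were 3 of 3 at E21, 1 at 30 min, 2 at 4 h, 2 at 12 h, 1 at 1 day and 1 at 7 days, so that number differed between E21 and each later age and was the same at 4 h as at 12 h and at 1 day as at 7 days. With the level of Ddx3y as a covariate 629 genes passed at 1 day, 571 of them shared with the 961, and 4 between 12 h and 1 day.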

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

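The tests of the 3 patterns weighed here, the genes named here outside the naming rule, such as Pnliprp1 and Ifit1, and the alternatives that use Y-linked expression or leave out several arrays together, were chosen after the result was seen.

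Features that no gene name or several names had kept out of the comparisons changed as well. Of 4916 such features 37 were higher than in E21 at 4 h, 65 at 12 h, 57 at 1 day and 212 at 7 days by the same limma test, and 31, 33, 32 and 275 were lower. At 30 min limma passed 0 of them, as it did of the named genes. Their median log2 intensity was 5.09 against 6.30 for features with 1 gene name. The largest rises at 7 days were in TC1500002296.rn.1 (3.80) and TC1800001331.rn.1 (3.77), and what they transcribe was not analysed here.

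E21 replicate 1 read Pck1, Tat and Sds, genes that glucagon and glucocorticoids induce, at 18.06, 17.95 and 14.69, far above the other E21 arrays and within the range of the 4 h arrays or near it. A mislabelled 30 min or 4 h array is argued against by its immediate early list, which lay 0.02 (0.0223) from the E21 mean where the 30 min arrays lay at 0.30 or more and the 4 h arrays at 0.47 or more. That mean includes the array itself. The median level of the list was 6.15 on it, 6.04 and 6.41 on the other E21 arrays, at least 6.57 at 30 min and at least 6.49 at 4 h. Of all arrays of other ages, its deviations from the age mean correlated most with those of 30 min replicate 3 (0.324). Over genes outside the metabolic lists the array stood at 0.294 of the way from the other E21 arrays to 4 h (and 0.246 to 12 h, 0.327 to 1 day and 0.00425 to 7 days). By the same measure the other E21 arrays stood at −0.05 and 0.16 and the 4 h arrays at 0.96, 1.09 and 0.51. In an earlier test a position under a bound was to argue against a 4 h array. The array lay above a first bound of 0.25 and above a second of 0.254, which is 50% of the lowest 4 h array. That test therefore did not argue against a mislabelled 4 h array, and the immediate early test was chosen after it. Whether it is a noisier array stays open, since 3 of the 18 arrays deviated more from their age mean, too few to argue against it. A longer wait or more stress of that dam or litter before sampling is a biological candidate explanation that the labels give no means to test.

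At 7 days, replicate 3 read high for pancreas genes and replicate 2 for skeletal muscle genes, from lists fixed before the data were examined. RNA from pancreas may account for the first, with 10 of 11 list genes raised by 1 or more and a median difference of 6.42 from the other 7 days arrays: Ctrb1 read 17.80, Pnliprp1 15.74, Cel 15.54 and Cpa1 14.74, although the lipase Pnlip, at 5.03, did not. RNA from skeletal muscle may account for the second, with 10 of 10 raised, a median difference of 3.61, Acta1 at 13.78 and Myh8 at 9.26. Male-tied expression at all ages is argued against, as the farthest other array with Y-linked expression lay at −0.22 from E21 in the pancreas list. At 7 days only replicate 3 expressed Y-linked genes, so sex there stays open. No biological explanation in liver was tested. List medians on other arrays were 4.62 to 5.22 for muscle and 4.48 to 4.84 for pancreas. For muscle all but 7 days replicate 2 and 4 h replicate 3 lay at 0.11 or less from the E21 mean. The latter lay at 0.35 and read Acta1, Myh8 and Myl1 at 7.31, 5.35 and 5.30, with no cause tested. The pancreas gene Cpb1 read 7.15 and 6.43 in 7 days replicates 1 and 2 and at most 5.04 at earlier ages.

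Arrays with Y-linked expression were 3 of 3 at E21 and 1 of 3 at 1 day and at 7 days. Sex of the pups as the whole cause of the calls is argued against by the fit with Ddx3y as a covariate, in which 59.4% of the calls at 1 day and 86.1% of those at 7 days remained, each in the same direction. In that fit 2 genes, Eif2s3 and Uty, followed the covariate, with 662 at an unadjusted p under 0.05. The covariate takes part of the difference between ages with it, so whether the other calls at 1 day could be due to sex or to the lower precision is open.

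For 30 min and other ages a few genes differed widely between arrays of one age. The standard deviation was above 2 log2 in at least 1 age for 73 genes and in at least 3 ages for 8, 3 of them the Y-linked Ddx3y, Eif2s3y and Kdm5d. Ifit1, an interferon-induced gene, read 11.43, 5.32 and 10.51 at E21 and 10.31, 11.07 and 5.06 at 1 day.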

How the results depend on the processing

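The Y-linked covariate, the replicate block of 2 ages alone and the alternatives that leave out 3 early arrays, 2 arrays of 7 days or genes near the upper limit were chosen after seeing the data, and all others were planned. Equal array medians, quantile normalization again, dim genes left out, every feature tested, the mean of features, the trended and robust prior and genes near the upper limit left out kept each count of genes within 1.5 times its value. No named gene turned its direction in an alternative where it passed there or in the main fit. Results that passed in neither were not checked for direction. Equal medians kept 244 of 246 gene results and 304 of 306 list results on the same side of the threshold. Quantile normalization kept 239 and 298, only the 6 arrays compared 166 and 278, and the replicate block 226 and 302. The Y-linked covariate kept 218 and 293, and leaving out single arrays 1174 of 1476 and 1631 of 1836. With an estimated correlation none of the 111 list calls was kept, and fry lost 64. A fit of only the 6 arrays compared, which has fewer residual degrees of freedom, gave 139 genes at 4 h and 297 at 1 day against E21, 1 from 30 min to 4 h, 1080 from 4 h to 12 h and 0 from 12 h to 1 day (1213 at an unadjusted p under 0.05 in limma over all 18 arrays). Array weights gave 15, 2244 and 2217 at 30 min, 4 h and 12 h, 1181, 3888 and 13 in the steps to 4 h, 12 h and 1 day, and 2 genes higher at 30 min for a time only; the cause was not tested. A log2 change of at least 1, a stricter rule by construction, left 296, 446, 387 and 1551 at 4 h, 12 h, 1 day and 7 days and 56, 650 and 1169 in the steps to 4 h, 12 h and 7 days. With the replicate number as a block over all ages 4 genes passed from 12 h to 1 day. Over all ages not every pair exceeds 0.1: residuals of 45 same-number pairs correlated at a median of −0.006 with 13 over 0.1, against 16 of 90 other pairs, and 9 of 18 arrays correlated best with an array of their own number, where chance gives 6. That is a hint from the data, not the design. In the 2 comparisons with all 3 pairs over 0.1, a block within the 2 ages gave 1028 genes at 4 h against E21 (822 of them shared with the 892) and 1746 from 4 h to 12 h (1570 shared with the 1684). It changed no list call, and of 51 named gene results it changed those of Pck1 (0.0362) and Blnk (0.0442) at 4 h, which passed, and of Sds from 4 h to 12 h (0.0642), which did not. The Y-linked covariate gave 629 genes at 1 day and 4 from 12 h to 1 day. Without the 3 early arrays 3 genes passed at 30 min, 1467 at 4 h and 445 from 30 min to 4 h, and the medians of cell cycle genes at 4 h and of immediate early genes from 30 min to 4 h turned to 0.21 and 0.10. Without 2 arrays of 7 days, which leaves 1 array there that is assumed to vary like those of other ages, 1807 genes passed against E21, 1006 against 1 day and 3095 over all ages, and the pancreas median against E21 and the muscle median against 1 day turned to −0.033 and −0.082; both arrays left out held the high values. Leaving out single arrays gave 0 to 8 genes at 30 min, 274 to 1371 at 4 h, 620 to 945 at 12 h, 425 to 875 at 1 day, 3228 to 3871 at 7 days and 4539 to 5999 over all ages, and in the steps 46 to 438, 883 to 1788, 3 to 12 and 2276 to 3120. The count of genes higher at 30 min for a time only was 0 in each, and 0 in limma over all arrays, where 1392 genes had an unadjusted p under 0.05 at 30 min. List medians that turned without 1 array ranged from −0.10 to 0.74 (cholesterol synthesis) and −0.11 to 0.47 (cytochromes P450) at 30 min, −0.26 to 0.18 (cell cycle) at 4 h, −0.38 to 0.17 (immediate early genes) and −0.21 to 0.26 (cell cycle) from 30 min to 4 h, −0.17 to 0.26 (ribosome biogenesis) from 12 h to 1 day, −0.036 to 1.70 (muscle) from 1 day to 7 days, and −0.078 to 3.48 (pancreas) at 7 days; the cause was not tested. Without an array an age has 2 of them and the test loses precision, and genes near the upper limit or the floor of the values show no or compressed change.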

Other observations

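The families in the next 2 paragraphs and their tests were chosen after the data were seen, while the splits of the arrays in the last paragraph were planned.

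Genes for histones and for the ribosome were lower at 7 days. Of 43 histone genes 29 were below E21 and 0 above (median −1.08, Fisher's exact test adjusted over 8 families and 9 comparisons, p = 2.8e-18), with H1f5 at −3.38 ± 0.47 and Hist1h4b at −2.55 ± 0.43. Of 69 genes of cytosolic ribosomal proteins 49 were lower and 0 higher (median −0.58, 3.6e-32), such as Rps19 at −1.17 ± 0.23 and Rplp0 at −0.90 ± 0.14, and 29 were lower without 7 days replicate 2 and 30 without E21 replicate 1. Erythroid, platelet and neutrophil markers (medians of −4.38, −3.17 and −2.57) and cell cycle genes fell in the same comparison. Neither a loss of blood-forming cells nor its part in the fall of these families was tested. At 1 day 0 genes of either family passed in limma (median 0.10 for histones and 0.05 for ribosomal proteins), and 2 ribosomal proteins were lower without 1 day replicate 3. Genes with proteasome symbols, which take in subunits, assembly factors and a few interacting proteins and pseudogenes, were higher at 1 day, 14 of 51 with 0 lower (median 0.45, 6.2e-08), among them the assembly factor Psmg1 (1.18 ± 0.21) and Psmd1 (0.98 ± 0.16), and 9 were higher and 1 lower at 12 h (0.00186). The 14 were 7 and 5 without E21 replicates 1 and 2 and 5 without 1 day replicate 3. The 9 were 5 and 4 without E21 replicates 1 and 2 and 3 and 5 without 12 h replicates 1 and 2. In camera with an estimated correlation none of the 72 tests of families passed, with an adjusted p of 0.661 for histones and ribosomal proteins at 7 days and the proteasome at 1 day, and 0.809 for the proteasome at 12 h.

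At 7 days 6 of 10 genes of MHC class II and 14 of 41 collagens were higher than at 1 day. Of 10 genes of MHC class II 6 were higher and 0 lower at 7 days than at E21 (median 0.97, Fisher's adjusted p = 0.00694), with RT1-Da at 3.88 ± 0.73 (at least 3.54) and the invariant chain Cd74 at 2.81 ± 0.53, beside the rise of macrophage markers. The median of those 6 was 0.91 in replicate 1, and 1.82 and 1.91 in replicates 2 and 3, which read high for muscle and pancreas genes. Without replicate 2 or without replicate 3, 5 were higher. Of 41 collagens 14 were higher and 0 lower at 7 days than at 1 day (median 0.21, 8.35e-05), with Col1a1 at 1.97 ± 0.56 and Col3a1 at 1.74 ± 0.26. The median of those 14 was 0.62 in replicate 1 and 1.34 and 1.12 in replicates 2 and 3, the arrays that read high for skeletal muscle and pancreas genes, and 11 collagens were higher without replicate 2 and 10 without replicate 3. Of 16 carboxylesterases 7 were higher than at E21 (0.0228), Ces1e at 2.84 ± 0.32 after Ces2e and Ces1c. With an estimated correlation the adjusted p was 0.661 for each of these 3. Genes with symbols of the respiratory chain and ATP synthase, some pseudogenes and the inhibitor Atp5if1 included (91 genes, 5 higher and 15 lower at 7 days), and transfer RNA synthetases (14 genes, 2 higher and 1 lower) were not enriched either way with all arrays, though Ndufa4l2 fell by 1.85 ± 0.18 (at least 0.34) and Cars1 was 1.57 ± 0.21. The 5 and 15 were 1 and 20, 4 and 6, and 4 and 7 without 7 days replicates 1, 2 and 3, and 1 and 10, 3 and 19, and 6 and 8 without E21 replicates 1, 2 and 3. For the synthetases they were 1 and 1 without E21 replicate 2 or 7 days replicate 3, and 2 and 0 without E21 replicate 1 or 7 days replicate 2. The medians named for these families kept their signs with equal array medians and with quantile normalization again, except those of ribosomal proteins at 1 day (−0.06 with quantile normalization) and of the synthetases at 7 days (0.08, and −0.003 with quantile normalization).

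Some of the values at 30 min differed between its arrays. Replicate 3 read Jun at 12.54 and Egr1 at 12.70, where replicates 1 and 2 read 8.97 and 9.37 and 9.08 and 11.28, while the hypoxia list lay at 0.98 and 0.60 in replicates 1 and 2 and at 0.17 in replicate 3. Acute phase proteins (0.52, 0.69 and 0.50) and fatty acid oxidation (−0.60, −0.39 and −0.55) were more alike on the 3. At 1 day replicate 3 read Trib3 at 12.54, Fgf21 at 10.92 and Chac1 at 8.69, genes that ATF4 induces, where the other 2 arrays read at most 7.39, 6.45 and 5.17. These genes were chosen after their values were seen, and no explanation was tested.

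Other groupings of the arrays were tried to see whether chance can be excluded. Over all ages chance is excluded: among 100 splits of the 18 arrays into 6 groups of 3, only the real 1 gave as many as 5931 genes, and the highest other gave 63. For 2 ages the 6 arrays make 10 splits, too few for a share under 0.05. The real split and the highest other gave 0 and 1 genes at 30 min, 892 and 1 at 4 h, 1124 and 1 at 12 h, 961 and 1 at 1 day and 4314 and 0 at 7 days against E21, and 186 and 29, 1684 and 0, 7 and 5, and 3441 and 0 in the steps to 4 h, 12 h, 1 day and 7 days. If the replicate numbers pair the arrays at 4 h against E21 and from 4 h to 12 h, which is not settled, 4 of the 10 splits part every pair. Beside the real one these gave at most 1 and 0 genes and 19 and 12 lists, and the splits that keep a pair together at most 1 and 0 genes and 18 and 17 lists. For list calls the real and highest other splits were 19 and 17, 15 and 19, 7 and 14, 14 and 19, and 17 and 25 against E21, and 5 and 15, 11 and 17, 3 and 12, and 20 and 21 in the steps. Splits as large as the real one, itself included, numbered 1, 5, 9, 2 and 5 of 10 for lists against E21 and 10, 5, 10 and 2 in the steps. From 30 min to 4 h and from 12 h to 1 day other splits called several times as many lists. With an estimated correlation none of the 111 list calls of the real splits was kept, so these calls depend on camera's preset of 0.01. The other splits were not run with an estimated correlation, and a structure among the arrays besides age was not tested.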
